A study of Drosophila melanogaster with 6 samples.

How the data were processed

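RNA was measured in whole heads of adult Drosophila melanogaster by sequencing after depletion of ribosomal RNA. The labels describe 2 groups of 3 biological replicates, wBerlin (a white-eyed control stock) and a knockout of Kdm3 (Kdm3 KO), with 50 heads per replicate from flies collected 2 to 7 days after eclosion and kept at 25 °C and 70% relative humidity. Ribosomal RNA was removed with a Ribo-Zero kit and libraries were made with a NEBNext Ultra II RNA kit, per the labels' protocols. Whether the replicates came from separate vials or crosses, the sex of the flies, and how the knockout allele was made are not given in the sources used here. The p-values therefore measure only the spread between these samples.

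The deposited table holds raw read counts per gene and library, made by the authors before deposit. STAR, SAMtools, HTSeq and DESeq2 and the genome build BDGP6 are named per the submitters' processing notes. Their versions, roles and settings are not given in the sources used here, and neither is whether the counting used strand. Genes that overlap on opposite strands and near-identical copies, such as the Amy and Hsp70 genes, are therefore uncertain as single genes. The table lists 17753 genes, of which 17626 matched a symbol and a position in the Ensembl release 115 annotation (BDGP6.54, the same assembly family as the authors' build) and 127 did not. All 301 listed genes of chromosome 4, the Y chromosome, the mitochondrial genome and unplaced scaffolds are at 0 in every library, so counts lie on the 5 arms 2L, 2R, 3L, 3R and X. Genes outside those arms, the mitochondrially encoded list among them, were not analysed here. Total counts were 28237382, 27468630 and 21935654 in wBerlin replicates 1, 2 and 3 and 25571878, 19850981 and 23926397 in Kdm3 KO replicates 1, 2 and 3. At these depths 3 counts correspond to between 0.106 and 0.151 CPM (counts scaled to library size), which is the level that a count of 0 allows. That limit covers counting error only, since reads made by PCR without molecular identifiers are not independent molecules. Libraries of the same group differed by a chi-square per degree of freedom of 16.8 to 65.8, so no library was a copy of another.

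From the deposited counts, differential expression was tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr by genotype with its default settings, glmQLFit and glmQLFTest, genotype as the only term, two-sided) with Benjamini-Hochberg adjustment over the 14069 genes that passed the filter. Genes with an adjusted p under 0.05 were called. All log2 fold changes are Kdm3 KO over wBerlin, and CPM values are scaled by TMM. The biological coefficient of variation was 18.2%. Principal components were computed on log2 CPM with a prior count of 2. Every adjusted p given for a gene is from edgeR's quasi-likelihood test with that adjustment unless another test is named. The replicate numbers were not used to pair libraries.

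Gene lists, named genes, tests and alternatives were chosen before the data were examined, except where stated otherwise. The named genes were Kdm3 and w, the 10 higher and the 10 lower called genes with the largest log2 fold change among those with a mean of at least 2 CPM and no overlap between the groups, up to 4 called members of each list by p (2 members by p where a list had none), and Sam-S, Gnmt, Ahcy and VGlut. Other genes given by name were chosen after their values were seen. The 30 lists covered one-carbon and S-adenosylmethionine (SAM) metabolism, glutamate, GABA, monoamine and acetylcholine signalling, synapse, glia, phototransduction, eye pigment, alcohol response, histone demethylases, histone methyltransferases, heterochromatin, clock, immune, stress, fat body, female-enriched, male-enriched, gut, muscle, hemocyte, detoxification, odorant binding, chemoreceptor, neuropeptide, ribosomal protein, mitochondrially encoded, nuclear oxidative phosphorylation and histone genes. The 7 lists added after the data were seen covered antennal receptors, soluble antennal proteins, Johnston's organ, maxillary palp receptors, purine synthesis, amino acid metabolism, and the Bomanin and Daisho peptides.

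Each list with at least 5 tested members was tested with camera (limma 3.58.1, voom values, preset correlation of 0.01). Adjustment was over the 29 tested lists fixed before the data were examined and, separately, over the 7 added lists. The same test with an estimated correlation, fry, and Fisher's exact test of called members against all other tested genes were run beside it, each adjusted over the same sets of lists. Fisher's exact test treats members as independent. Its p is therefore too small for lists whose members vary together, such as the one-carbon list (estimated correlation 0.619), and is no separate support there. Members were also counted with p adjusted over the list alone. Called and not called genes were compared by position with two-sided Fisher's exact tests for each arm and for a window of 2 Mb on either side of Kdm3, with 95% confidence intervals of the odds ratio.

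The procedure was tested on simulated counts for the comparison of Kdm3 KO with wBerlin, drawn for 14069 genes with 100 genes changed 2-fold and 100 changed 4-fold. The changed genes were picked among those with a mean of at least 2 CPM, so recovery at lower levels was not tested. The procedure called 78% of the genes changed 2-fold and 99% of those changed 4-fold in the right direction, and 5.85% of its calls were unchanged genes. With no gene changed it made 0 calls, and 0 of 40 unchanged lists passed the threshold. The simulated genes were drawn independently, so this says nothing about lists whose members vary together. In the real libraries the estimated correlation within lists fixed before the data were examined reached 0.787, and splits of the libraries that mix the genotypes gave 9 to 19 lists past the threshold, against 15 for the real split. The alternatives were DESeq2 1.42.0, limma voom, RLE, upper quartile and total count scaling, no filter on low counts, a filter of 5 CPM in 3 libraries, removal of ribosomal RNA and mitochondrial genes, a replicate block, stricter thresholds, windows of 1 and 5 Mb, and each library left out in turn. A fit of the 4 libraries left without wBerlin replicate 1 and Kdm3 KO replicate 2 was added after the data were seen. So was camera with 3 lists shortened, the immune list without Bomanin and Daisho genes, the female-enriched list without fat body genes and the histone demethylase list without Kdm3. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.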

Results

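Gene expression was compared between heads of Kdm3 KO flies and heads of the wBerlin control, with 3 libraries per genotype and 19850981 to 28237382 counts per library. Kdm3 encodes a JmjC-domain histone demethylase that acts on methylated lysine of histone H3. The comparison asks how loss of Kdm3 changes head transcripts, in a study of the one-carbon cycle, methylation and alcohol responses. Any other genetic difference between the knockout and control stocks would appear in this comparison as well.

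The targeted gene Kdm3 (FBgn0037703, chromosome arm 3R, 9516007 to 9520938, BDGP6) was measured at 30.45 ± 1.90 CPM (SD, n = 3) in wBerlin and 1.74 ± 1.84 CPM (SD, n = 3) in Kdm3 KO. It fell by 4.09 on the log2 scale (SE 0.49, adjusted p = 0.00344). The 3 knockout libraries held 3.86, 0.642 and 0.710 CPM in replicates 1, 2 and 3, and the lowest control library 28.7 CPM. The eye pigment transporter gene w (arm X, 2790599 to 2796466) rose from 1.62 ± 0.150 to 24.7 ± 3.71 CPM (SD, n = 3), 15.2-fold (adjusted p = 3.91e-06). The control stock is white-eyed. How the Kdm3 allele was made is not given in the sources used here, so it is unresolved whether these reads come from the gene on arm X or from a w marker in the allele.

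**Figure D1:**
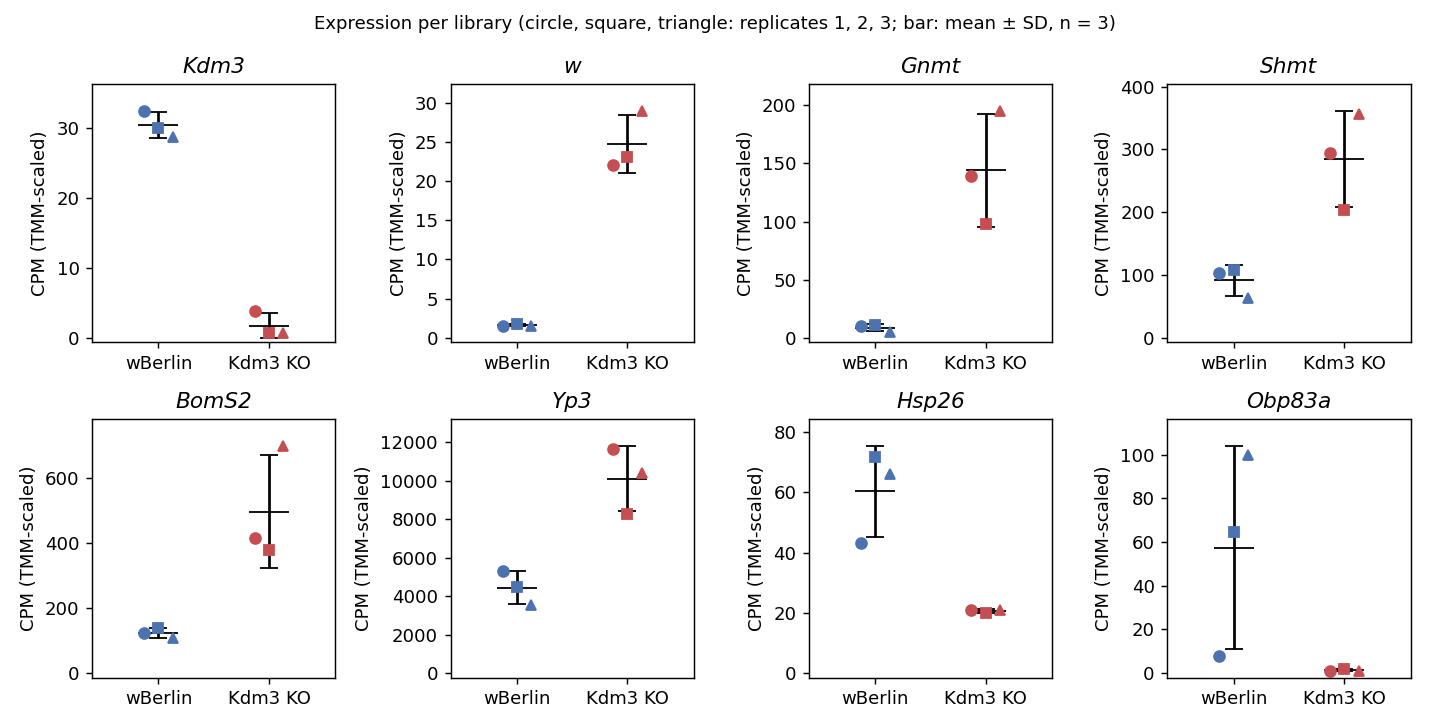
CPM (TMM-scaled) of 8 genes in each of the 6 libraries, with wBerlin in blue, Kdm3 KO in red, symbols for replicates 1, 2 and 3, and bars for the mean ± SD (n = 3). Kdm3 sat at 28.7 CPM or more in wBerlin and at 3.86 CPM or less in Kdm3 KO, and Obp83a was at 7.76 CPM in wBerlin replicate 1 against 64.6 and 99.9 CPM in replicates 2 and 3.

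In Kdm3 KO heads 303 genes were higher and 129 lower than in wBerlin by edgeR's quasi-likelihood test, and 158 and 49 of them differed at least 2-fold. The largest increases among genes with a mean of at least 2 CPM were in the noncoding RNA lncRNA:CR40469 (arm X, 122493 to 122706) and in CG16826, whe, CG40486, CG4757, CG45080, Gnmt, w, Osi2 and asRNA:CR45600. The level of lncRNA:CR40469 rose 73.9-fold from 8.82 ± 2.21 to 652 ± 109 CPM (SD, n = 3, adjusted p = 3.72e-06), and the other 9 rose 12.2- to 56.6-fold. The antisense RNA asRNA:CR45600 overlaps the end of CG6912, which was also 7.26-fold higher. In Kdm3 KO, CG16826 was at 58.2 and 48.8 CPM in replicates 1 and 2 but 6.70 CPM in replicate 3, and whe and CG45080 were also lowest in replicate 3. The 10 lower genes chosen by the same rule were Obp83b, a10, Os-C, Obp83a, Obp19a, CG4440, a5, Kdm3, Acsx2 and Tom. Tom was at 10.9, 21.7 and 2.98 CPM in wBerlin replicates 1, 2 and 3. Acsx2 was at 4.88, 45.7 and 52.0 CPM in these libraries and at 3.02, 4.59 and 3.46 CPM in Kdm3 KO. Its level in wBerlin replicate 1 was thus close to that of Kdm3 KO.

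Several of these calls ended in other fits, while the fold stayed large. These include a fit of the 4 libraries left without wBerlin replicate 1 and Kdm3 KO replicate 2, a choice made after the data were seen. The call of CG45080 ended without wBerlin replicates 1, 2 or 3 or Kdm3 KO replicate 2 (adjusted p 0.0584, 0.113, 0.0842 and 0.0568) and in the 4 libraries (0.102). Its log2 fold change was 3.68 to 4.17 in these fits against 4.15. That of whe ended without wBerlin replicate 2 (adjusted p 0.05) and in the 4 libraries (0.0630), at 4.70 to 5.35 against 5.02. The call of CG4440 ended without wBerlin replicate 2 or Kdm3 KO replicates 1, 2 or 3 (adjusted p 0.125, 0.0609, 0.0744 and 0.102) and with upper quartile scaling, total count scaling and in the 4 libraries (0.0511, 0.0539 and 0.0793), at −5.35 to −3.36 against −4.45. For Tom the call ended without wBerlin replicates 1 or 2 or Kdm3 KO replicates 1 or 3 (adjusted p 0.0693, 0.180, 0.0954 and 0.144) and with RLE scaling, upper quartile scaling, total count scaling and in the 4 libraries (0.0518, 0.0764, 0.0796 and 0.0630), at −4.21 to −2.45 against −3.21. For Acsx2 it ended without wBerlin replicates 2 or 3 or Kdm3 KO replicates 1, 2 or 3 (adjusted p 0.144, 0.111, 0.0894, 0.101 and 0.129) and with upper quartile scaling, total count scaling and the filter of 5 CPM (0.0636, 0.0675 and 0.0564), at −3.39 to −2.83 against −3.21. A fit with a library left out has only 2 libraries in that group, which by itself lowers power. The fits without wBerlin replicate 1 or Kdm3 KO replicate 2 still gave more calls in total (735 and 726 against 432), so power need not explain the losses there. Limma voom did not call CG16826 (adjusted p = 0.290) or these 5 genes. Of the 303 higher and 129 lower genes together, 431 of 432 had no overlap between the libraries of the 2 groups, and over all tested genes 18.7% had none, where chance gives 10%. Leaving out a library gave 268 higher and 467 lower genes without wBerlin replicate 1, 181 and 62 without wBerlin replicate 2, and 192 and 158 without wBerlin replicate 3. Without Kdm3 KO replicate 1 the numbers were 245 and 80, without replicate 2 574 and 152, and without replicate 3 201 and 66. The first principal component (44.1% of the variance) set Kdm3 KO replicate 2 apart from the other 5 libraries, and the second (31.6%) separated the genotypes.

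Genes of one-carbon and SAM metabolism were higher in Kdm3 KO. Of 28 tested members 10 rose and 0 fell (16 and 1 list-adjusted, with p adjusted over the list alone, 18 and 1 at an unadjusted p under 0.05, 15 and 0 by DESeq2, 10 and 0 by voom, 14 and 0 in the 4 libraries). Glycine N-methyltransferase, Gnmt (FBgn0038074, arm 3R, 12674608 to 12676084), which uses SAM to methylate glycine to sarcosine, rose 16.5-fold from 8.66 ± 3.12 to 144 ± 48.9 CPM (SD, n = 3). Its log2 fold change was 4.04 (SE 0.32, adjusted p = 0.000448). Sarcosine dehydrogenase, Sardh (arm 2R, 17753555 to 17756422), which turns sarcosine back into glycine, rose 2.78-fold from 22.4 ± 5.55 to 62.4 ± 12.3 CPM (SD, n = 3, adjusted p = 0.00500). Serine hydroxymethyltransferase, Shmt (arm X, 5913067 to 5916797), rose 3.11-fold from 91.4 ± 24.5 to 285 ± 76.5 CPM (SD, n = 3, adjusted p = 0.00700). CG10621, annotated as a homocysteine methyltransferase, and the folate genes Mthfs, CG8665 and pug rose 2.15-, 2.43-, 2.17- and 2.12-fold. Adi1, Adk2 and SamDC had log2 fold changes of 0.59, 0.58 and 0.54. Each of these 3 calls ended without wBerlin replicates 1, 2 or 3 or Kdm3 KO replicates 1 or 3 (adjusted p 0.0515 to 0.141). The SAM synthetase Sam-S was at 332 ± 15.9 and 445 ± 48.8 CPM (SD, n = 3) in wBerlin and Kdm3 KO (adjusted p = 0.0890). Adenosylhomocysteinase, Ahcy, was at 33.6 ± 4.39 and 49.4 ± 9.63 CPM (SD, n = 3, adjusted p = 0.0955) and neither passed the test. Both rose by DESeq2, with upper quartile scaling, total count scaling and the filter of 5 CPM, without Kdm3 KO replicate 2 and in the 4 libraries. The adjusted p in these 6 settings were 0.00210, 0.0138, 0.0115, 0.0106, 0.0121 and 0.0114 for Sam-S and 0.0110, 0.0471, 0.0420, 0.0414, 0.0280 and 0.0360 for Ahcy. The list's median log2 fold change was 0.50, 0.37 to 0.63 with 1 library left out (camera adjusted p = 1.10e-11, adjusted p = 0.595 with an estimated correlation, Fisher's exact test adjusted p = 5.19e-08). Without Kdm3 KO replicate 2 alone 14 members were higher, and without wBerlin replicates 1, 2 or 3 or Kdm3 KO replicates 1 or 3 7.

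Fat body genes were higher as well, and none of them is in the one-carbon list. Of 47 tested fat body genes 15 rose and 1 fell (23 and 2 list-adjusted, 24 and 2 unadjusted, 21 and 1 by DESeq2, 14 and 1 by voom, 18 and 0 in the 4 libraries). Pepck2, which makes phosphoenolpyruvate, rose 3.05-fold from 63.0 ± 7.64 to 192 ± 41.3 CPM (SD, n = 3, adjusted p = 0.00129). The insulin-like peptide gene Ilp6 rose 1.92-fold (adjusted p = 0.00227). The amylase genes Amy-p and Amy-d, near-identical copies whose reads may be shared, rose 9.57- and 4.97-fold. The list had a median log2 fold change of 0.47, 0.33 to 0.59 with 1 library left out (camera adjusted p = 3.83e-12, adjusted p = 0.595 with an estimated correlation, Fisher's exact test adjusted p = 8.64e-12). With 1 library left out the number of higher members was lowest without wBerlin replicate 2 (10) and Kdm3 KO replicate 3 (12) and highest without Kdm3 KO replicate 2 (19). Of 18 female-enriched transcripts 2 rose, Yp3 and fit, and 0 fell (4 and 0 list-adjusted, 4 and 0 unadjusted, 4 and 0 by DESeq2, 2 and 0 by voom, 4 and 0 in the 4 libraries). Both are among the 4 that are also in the fat body list, and 0 of the 14 others passed. The yolk protein gene Yp3 rose 2.27-fold from 4446 ± 870 to 10100 ± 1690 CPM (SD, n = 3, adjusted p = 0.0109), and fit rose 3.62-fold (adjusted p = 0.00557). The call of Yp3 ended without wBerlin replicate 2 (adjusted p 0.0773), and 4 members rose without wBerlin replicate 1. Camera called the female-enriched list (camera adjusted p = 0.00477, adjusted p = 0.726 with an estimated correlation). This call ended without Kdm3 KO replicate 2 or in the 4 libraries (0.734 and 0.837, range 6.28e-05 to 0.837 over 10 alternatives). The median was 0.58, −0.16 without Kdm3 KO replicate 2 and −0.20 in the 4 libraries. Camera did not call the 14 genes outside the fat body list, a split made after the data were seen (median 0.47, camera adjusted p = 0.446, adjusted p = 0.963 with an estimated correlation). The male-specific RNAs roX1 and roX2 had log2 fold changes of 0.42 (SE 0.13) and 0.59 (SE 0.14) and did not pass the test (adjusted p 0.141 and 0.0539). Of 18 male-enriched genes 0 rose and 1 fell (3 and 1 list-adjusted, 3 and 1 unadjusted, 2 and 1 by DESeq2, 0 and 1 by voom, 0 and 0 in the 4 libraries). The gene that fell was takeout, to, at 0.58 of the control level (adjusted p = 0.0326), which is also the 1 fat body gene that fell. Its call ended without wBerlin replicates 1 or 2 or Kdm3 KO replicates 2 or 3 (adjusted p 0.0541, 0.108, 0.0776 and 0.115) and in the 4 libraries (0.107). There was 1 male-enriched gene higher without wBerlin replicate 3 or Kdm3 KO replicates 1 or 2. The male-enriched median was 0.13, −0.08 to 0.31 with 1 library left out, and −0.0123 by limma voom (camera adjusted p = 0.734).

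Gut and muscle transcripts differed between libraries of 1 genotype. Kdm3 KO replicate 2 held the flight muscle genes TpnC4 at 87.8 CPM, Act88F at 1276 CPM and fln at 14.4 CPM, where the other 5 libraries had at most 2.26, 247 and 1.01 CPM. The summed gut list was 325 CPM in that library and 98.9 to 183 CPM in the others. Of 32 gut genes 2 rose, Amy-p and Amy-d, and 0 fell (4 and 0 list-adjusted, 6 and 0 unadjusted, 3 and 0 by DESeq2, 2 and 0 by voom, 3 and 0 in the 4 libraries). Camera put the gut list higher (camera adjusted p = 0.0232, adjusted p = 0.917 with an estimated correlation). This call ended without wBerlin replicate 1 (0.0524), and the direction turned without Kdm3 KO replicate 2 or in the 4 libraries (0.339 and 0.106, range 5.56e-05 to 0.339 over 9 alternatives). Of 33 muscle genes 1 fell and 0 rose (11 and 1 list-adjusted, 16 and 2 unadjusted, 9 and 0 by DESeq2, 1 and 0 by voom, 18 and 0 in the 4 libraries). Act87E fell by 1.44 on the log2 scale, from 736 ± 305 to 272 ± 78.1 CPM (SD, n = 3, adjusted p = 0.0409). Its call ended without wBerlin replicates 2 or 3 or Kdm3 KO replicates 1, 2 or 3 (adjusted p 0.126, 0.0983, 0.0834, 0.0872 and 0.0718) and with upper quartile scaling, total count scaling and the filter of 5 CPM (0.0600, 0.0653 and 0.0539). The muscle list had a median log2 fold change of −0.51, −0.75 to −0.34 with 1 library left out (camera adjusted p = 3.51e-09, adjusted p = 0.595 with an estimated correlation). Lower members numbered 14 without wBerlin replicate 1, 11 with the replicate block, 0 without wBerlin replicates 2 or 3 or Kdm3 KO replicates 1, 2 or 3, and 0 with upper quartile or total count scaling or the filter of 5 CPM. The list's summed level in wBerlin replicate 1, 42870 CPM, lay below the 62800 and 75840 CPM of replicates 2 and 3 and within the 34190, 46430 and 43980 CPM of Kdm3 KO.

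**Figure D2:**
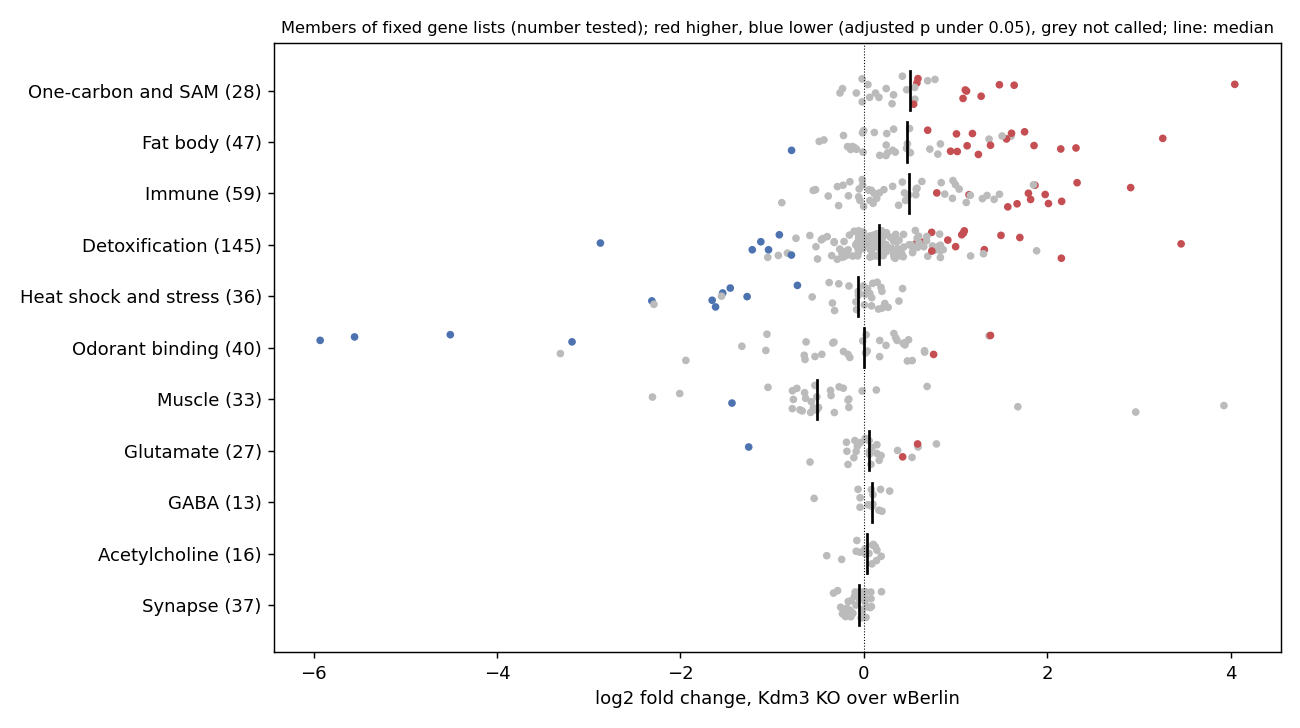
Log2 fold change (Kdm3 KO over wBerlin, horizontal axis) of every tested member of 11 gene lists, with members higher in red, lower in blue (adjusted p under 0.05) and not called in grey, and a vertical line at each list's median. Of the one-carbon list 10 of 28 members were higher and 0 lower, and of the stress list 0 were higher and 7 lower.

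Of 59 tested immune genes 12 rose and 0 fell (19 and 2 list-adjusted, 22 and 3 unadjusted, 18 and 1 by DESeq2, 12 and 0 by voom, 15 and 1 in the 4 libraries). Of these 12, 11 code for Bomanin and Daisho peptides, which the Toll pathway induces, and the other is the recognition gene PGRP-SD (1.73-fold, adjusted p = 0.0154), whose call ended without wBerlin replicate 2 (adjusted p 0.0651). BomBc3 (arm 3R, 22087075 to 22088501) rose 7.51-fold from 10.2 ± 1.84 to 77.0 ± 27.2 CPM (SD, n = 3, adjusted p = 0.000551). BomS2 (arm 2R, 18386602 to 18387030) rose 4.03-fold from 123 ± 14.7 to 496 ± 174 CPM (SD, n = 3, adjusted p = 0.00227). The genes BomS1 and BomT2 rose 3.47- and 3.64-fold. The antimicrobial peptide genes Drs, DptA and AttA did not pass the test. Their log2 fold changes were 1.85 (SE 0.42, adjusted p = 0.05025) for Drs, 0.97 (SE 0.72, adjusted p = 0.629) for DptA and −0.53 (SE 0.48, adjusted p = 0.701) for AttA. The immune list's median was 0.49, 0.34 to 0.64 with 1 library left out (camera adjusted p = 1.29e-08, adjusted p = 0.595 with an estimated correlation, Fisher's exact test adjusted p = 1.32e-06). Without the Bomanin and Daisho genes, a split made after the data were seen, the 48 other immune genes had a median of 0.27 (camera adjusted p = 0.0177, adjusted p = 0.963 with an estimated correlation). The fat body, a main source of immune peptides, had a list median close to that of the immune list (0.47 and 0.49), so a larger share of its RNA was not excluded for the immune list. Of 16 hemocyte genes 2 rose, NimB4 and PPO1, and 0 fell (2 and 0 list-adjusted, 4 and 0 unadjusted, 2 and 0 by DESeq2, 2 and 0 by voom, 2 and 0 in the 4 libraries). None rose without wBerlin replicates 2 or 3 or Kdm3 KO replicates 1 or 3. The call of NimB4 ended without wBerlin replicates 2 or 3 or Kdm3 KO replicates 1 or 3 (adjusted p 0.137, 0.0996, 0.102 and 0.123). That of PPO1 ended without wBerlin replicates 1, 2 or 3 or Kdm3 KO replicates 1 or 3 (adjusted p 0.0860, 0.152, 0.0582, 0.0914 and 0.0959) and with no filter on low counts and in the 4 libraries (0.0529 and 0.0519). Camera did not call the hemocyte list (camera adjusted p = 0.0581), apart from the fits without wBerlin replicate 1 or Kdm3 KO replicate 2 (0.0264 and 0.00470), of the 4 libraries (0.00186) and with the filter of 5 CPM (0.0433, range 0.00186 to 0.513 over 10 alternatives).

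Of 36 tested stress genes 7 fell, 6 heat shock genes and the co-chaperone gene stv, and 0 rose (11 and 2 list-adjusted, 12 and 2 unadjusted, 10 and 2 by DESeq2, 6 and 0 by voom, 8 and 3 in the 4 libraries). The list has 16 members with a positive log2 fold change, and no list of heat shock genes alone was tested. The small heat shock gene Hsp26 (arm 3L, 9376418 to 9377427) fell 2.91-fold from 60.2 ± 15.01 to 20.7 ± 0.611 CPM (SD, n = 3, adjusted p = 0.00227). Hsp68 fell 2.75-fold from 146 ± 38.6 to 53.1 ± 5.15 CPM (SD, n = 3, adjusted p = 0.00392). Hsp70Bb and Hsp70Ab, near-identical copies, fell 4.97- and 3.07-fold, and stv 1.65-fold. On arm 3R, Hsp70Ab, Hsp70Bb and Hsp70Bc lie 2.44, 2.99 and 2.99 Mb from Kdm3, while Hsp68 lies farther off. For these Hsp70 genes, sequence linked to the Kdm3 allele cannot be told apart from an effect of Kdm3 loss. The call of Hsp27 ended without wBerlin replicates 2 or 3 or Kdm3 KO replicates 1 or 3 (adjusted p 0.157, 0.102, 0.0782 and 0.113) and with upper quartile scaling, total count scaling and the filter of 5 CPM (0.0720, 0.0779 and 0.0564). That of Hsp70Bc ended without wBerlin replicate 2 (adjusted p 0.0597) and with limma voom (0.0643). The constitutive Hsc70-4 had a log2 fold change of −0.16 (SE 0.14, adjusted p = 0.694). The stress list's median was −0.06, −0.13 to 0.04 with 1 library left out (camera adjusted p = 0.00300, adjusted p = 0.704 with an estimated correlation, Fisher's exact test adjusted p = 0.000549). Its camera call ended without Kdm3 KO replicate 2 (0.440), where 8 members were lower and 3 higher and the median was 0.04. It also ended in the 4 libraries and with the filter of 5 CPM (0.274 and 0.256, range 6.28e-05 to 0.440 over 10 alternatives).

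Detoxification genes went both ways. Of 145 tested 15 rose and 6 fell (26 and 8 list-adjusted, 37 and 16 unadjusted, 25 and 7 by DESeq2, 13 and 5 by voom, 24 and 11 in the 4 libraries). The glutathione transferase gene GstD3 rose 4.45-fold from 2.37 ± 0.394 to 10.6 ± 0.179 CPM (SD, n = 3, adjusted p = 0.000238). Ugt37A3 and Ugt35B1 rose 10.99- and 2.14-fold, and the cytochrome P450 gene Cyp9f3 fell 2.18-fold. On arm 3R, GstD3, Ugt37A3, Ugt35B1 and Cyp9f3 lie 2.85, 3.22, 1.65 and 2.88 Mb from Kdm3. For these genes, sequence linked to the Kdm3 allele cannot be told apart from an effect of Kdm3 loss. Limma voom did not call Ugt37A3 (adjusted p = 0.0566). The list's median log2 fold change was 0.17, 0.09 to 0.17 with 1 library left out (camera adjusted p = 0.00348, adjusted p = 0.595 with an estimated correlation, Fisher's exact test adjusted p = 4.78e-08). The list was not called by camera in the 4 libraries (0.0558, range 0.000441 to 0.0558 over 10 alternatives). The number of higher members was 24 without Kdm3 KO replicate 2. The number of lower members was 11 without wBerlin replicate 1, 3 without Kdm3 KO replicate 2, and 2 without wBerlin replicate 2 or Kdm3 KO replicate 3.

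Odorant-binding genes expressed in the antenna were lower in Kdm3 KO and also in wBerlin replicate 1. Of 40 tested odorant-binding genes 2 rose and 4 fell (6 and 9 list-adjusted, 7 and 12 unadjusted, 3 and 6 by DESeq2, 2 and 0 by voom, 5 and 11 in the 4 libraries). Obp83a (arm 3R, 5972155 to 5975245) was at 7.76, 64.6 and 99.9 CPM in wBerlin replicates 1, 2 and 3 and at 0.914, 1.74 and 1.02 CPM in Kdm3 KO. Its log2 fold change was −5.55 (SE 0.86, adjusted p = 0.00868). Those of Obp83b and Obp19a were −5.93 and −4.51, and those of the antennal genes a10, Os-C and a5 −5.71, −5.57 and −4.35. Orco, the coreceptor of most odorant receptors, was at 6.36, 26.5 and 37.0 CPM in wBerlin and 3.66, 5.73 and 5.19 CPM in Kdm3 KO, and did not pass the test (adjusted p = 0.0508). Limma voom called none of the 6 genes (highest adjusted p 0.478 for a5). The call of Obp19a ended without wBerlin replicates 2 or 3 or Kdm3 KO replicates 2 or 3 (adjusted p 0.0754, 0.0583, 0.0510 and 0.0808). For Os-C the call ended without wBerlin replicate 2 or Kdm3 KO replicate 3 (adjusted p 0.0602 and 0.0645). For a5 it ended without wBerlin replicates 2 or 3 or Kdm3 KO replicates 1, 2 or 3 (adjusted p 0.111, 0.0992, 0.0686, 0.0597 and 0.115) and with upper quartile scaling and total count scaling (0.0537 and 0.0560). Obp99c, which is also in the fat body list, rose 2.60-fold from 209 ± 61.5 to 544 ± 124 CPM (SD, n = 3, adjusted p = 0.0137). Obp83ef rose 1.69-fold, and its call ended without wBerlin replicates 2 or 3 or Kdm3 KO replicate 3 (adjusted p 0.105, 0.0705 and 0.0571). The odorant-binding list had a median of 0.00, −0.15 to 0.03 with 1 library left out, slightly below 0 with upper quartile scaling (−0.004), and a mean of −0.57. Camera put it lower without calling it (camera adjusted p = 0.779, Fisher's exact test adjusted p = 0.00620) and higher, also without a call, without wBerlin replicates 2 or 3 or Kdm3 KO replicate 2 (0.791, 0.626 and 0.747). With the replicate block camera called it lower (0.0459, range 0.0459 to 0.975 over 10 alternatives). Lower members numbered 10 without wBerlin replicate 1 and 2 without wBerlin replicates 2 or 3 or Kdm3 KO replicates 2 or 3. Higher members numbered 1 without wBerlin replicates 2 or 3 or Kdm3 KO replicate 3 and 4 without Kdm3 KO replicate 2.

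Chemoreceptor genes mostly did not pass the test. Of 166 tested, 1 rose, Or82a at 0.924 ± 0.208 and 2.86 ± 1.00 CPM (SD, n = 3) in wBerlin and Kdm3 KO (adjusted p = 0.0340), and 0 fell (0 and 0 list-adjusted, 4 and 6 unadjusted, 1 and 2 by DESeq2, 0 and 0 by voom, 1 and 10 in the 4 libraries). The call of Or82a ended without wBerlin replicates 1, 2 or 3 or Kdm3 KO replicate 1 (adjusted p 0.107, 0.188, 0.0980 and 0.0640) and with limma voom, upper quartile scaling, total count scaling and no filter on low counts (0.0592, 0.0593, 0.0577 and 0.0505). Of all members 2 fell without wBerlin replicate 1 and 3 without Kdm3 KO replicate 2. The median was 0.21, but −0.23 without Kdm3 KO replicate 2 and −0.34 in the 4 libraries. Camera did not call the list (camera adjusted p = 0.708), but put it higher without Kdm3 KO replicate 3 (0.00340) and lower without Kdm3 KO replicate 2 or in the 4 libraries (0.00132 and 1.34e-05, range 1.34e-05 to 0.994 over 10 alternatives).

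Most neurotransmitter genes did not pass the test. Of 27 glutamate genes 2 rose and 1 fell (4 and 1 list-adjusted, 4 and 2 unadjusted, 4 and 1 by DESeq2, 1 and 0 by voom, 3 and 2 in the 4 libraries). The list was not called by camera (median 0.06, −0.03 to 0.06 with 1 library left out, camera adjusted p = 0.454). Glutamine synthetase 1, Gs1, rose by 0.59 on the log2 scale from 217 ± 3.30 to 325 ± 49.0 CPM (SD, n = 3, adjusted p = 0.0336). The kainate receptor auxiliary gene Neto rose 1.34-fold (adjusted p = 0.0452), and the kainate-type receptor gene Grik fell 2.39-fold (adjusted p = 0.0449). The call of Gs1 ended without wBerlin replicates 2 or 3 or Kdm3 KO replicates 1 or 3 (adjusted p 0.0975, 0.0679, 0.0898 and 0.0959). The call of Neto ended without wBerlin replicates 1, 2 or 3 or Kdm3 KO replicates 1, 2 or 3 (adjusted p 0.0814, 0.169, 0.0620, 0.0565, 0.0548 and 0.142) and with limma voom and in the 4 libraries (0.0510 and 0.0759). For Grik it ended without wBerlin replicates 2 or 3 or Kdm3 KO replicates 1, 2 or 3 (adjusted p 0.159, 0.117, 0.107, 0.0656 and 0.139) and with limma voom, upper quartile scaling, total count scaling and the filter of 5 CPM (0.0645, 0.0774, 0.0833 and 0.0669). No glutamate gene passed without wBerlin replicates 2 or 3 or Kdm3 KO replicates 1 or 3, 1 rose and 2 fell without wBerlin replicate 1, and 3 rose and 0 fell without Kdm3 KO replicate 2. The vesicular glutamate transporter VGlut was at 542 ± 62.0 and 572 ± 52.4 CPM (SD, n = 3) in wBerlin and Kdm3 KO (log2 fold change 0.08, SE 0.12, adjusted p = 0.843). The NMDA receptor gene Nmdar1 had a log2 fold change of 0.09 (SE 0.11, adjusted p = 0.791).

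By edgeR 0 of 13 GABA, 0 of 16 acetylcholine, 0 of 37 synapse and 0 of 24 glial genes passed, and adjusted over the list alone 0, 0, 0 and 3 did. At an unadjusted p under 0.05 the numbers were 2, 2, 2 and 3, DESeq2 called 1, 1, 0 and 3, voom called 0 in each, and 4, 0, 0 and 5 passed in the 4 libraries. The glial genes rumpel and alrm had log2 fold changes of 0.47 and 0.49 (adjusted p 0.0541 and 0.0781), and both rose in 8 settings. These were DESeq2 (0.00358 and 0.00452), upper quartile scaling (0.0120 and 0.0286), total count scaling (0.01005 and 0.0242), the filter of 5 CPM (0.0101 and 0.0211), the replicate block (0.0215 and 0.0233), the fits without wBerlin replicate 1 (0.0449 and 0.0466) or Kdm3 KO replicate 2 (0.00830 and 0.0140) and the 4 libraries (0.00849 and 0.00745). With RLE scaling rumpel alone rose (0.0454). Without wBerlin replicate 1, the GABA gene b was lower (0.0065), and 2 glial genes were higher and 1 lower. Without wBerlin replicate 3, the acetylcholine gene nAChRbeta1 and the synapse gene fne were lower (0.02525 and 0.0488). Without Kdm3 KO replicate 2, the GABA gene Ssadh (0.0361) and 2 glial genes were higher. In the 4 libraries 3 GABA genes were higher and 1 lower, and 4 glial genes were higher and 1 lower. Camera put the synapse list lower (median −0.05, −0.19 to −0.02 with 1 library left out, camera adjusted p = 0.0232, adjusted p = 0.917 with an estimated correlation). The synapse call ended without wBerlin replicate 1 (0.406) or Kdm3 KO replicate 2 (0.433), in the 4 libraries (0.220) or with the filter of 5 CPM (0.0975, range 1.07e-05 to 0.433 over 10 alternatives). The GABA, acetylcholine and glial lists did not pass camera (adjusted p 0.388, 0.804 and 0.104), apart from the glial list without Kdm3 KO replicate 2 (0.000672) and all 3 lists in the 4 libraries. There camera called the GABA list higher (0.00580, range 0.00580 to 0.805 over 10 alternatives), as well as the acetylcholine list (0.0245, range 0.0245 to 0.999 over 10 alternatives) and the glial list (0.000241, range 0.000241 to 0.646 over 10 alternatives).

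Among 30 monoamine genes 1 rose and 0 fell (2 and 1 list-adjusted, 2 and 1 unadjusted, 1 and 1 by DESeq2, 1 and 0 by voom, 1 and 1 in the 4 libraries). This was phenylalanine hydroxylase, Hn, which rose 2.06-fold from 176 ± 16.2 to 361 ± 74.6 CPM (SD, n = 3, adjusted p = 0.00751). Without wBerlin replicate 1 or Kdm3 KO replicate 2 1 monoamine gene fell, and camera did not call the list (camera adjusted p = 0.797), except as higher in the 4 libraries (0.0298, range 0.0298 to 0.903 over 10 alternatives). Among 47 neuropeptide genes 1 rose, Ilp6, and 0 fell (1 and 0 list-adjusted, 2 and 4 unadjusted, 2 and 1 by DESeq2, 1 and 0 by voom, 3 and 1 in the 4 libraries). In that list 1 gene was lower without wBerlin replicate 1. This list's median of 0.02 (−0.10 to 0.04 with 1 library left out) and mean of 0.04 were positive while camera gave the direction as lower (camera adjusted p = 0.975), and as higher without wBerlin replicate 1 or Kdm3 KO replicate 2 (0.133 and 0.548). In the 4 libraries camera called it higher (0.0365, range 0.0365 to 0.992 over 10 alternatives).

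Of 53 genes with a known role in alcohol response 1 rose, alcohol dehydrogenase, Adh, and 0 fell (1 and 0 list-adjusted, 5 and 1 unadjusted, 4 and 1 by DESeq2, 1 and 0 by voom, 5 and 1 in the 4 libraries). Adh was 1.58-fold higher, from 21.8 ± 0.834 to 34.5 ± 6.30 CPM (SD, n = 3, adjusted p = 0.0320). Its call ended without wBerlin replicates 1, 2 or 3 or Kdm3 KO replicates 1 or 3 (adjusted p 0.0507, 0.0898, 0.0890, 0.0898 and 0.110). Without Kdm3 KO replicate 2, 4 alcohol genes rose and 1 fell, and 1 fell without wBerlin replicates 1 or 3. The alcohol list had a median of −0.05, −0.13 to 0.01 with 1 library left out and camera did not call it (camera adjusted p = 0.388), except without wBerlin replicate 3 or Kdm3 KO replicate 3 (0.0275 and 0.0424, range 0.0275 to 0.551 over 10 alternatives).

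Of 20 eye pigment genes 4 rose, ry, Hn, v and w, the last with the source of its reads unresolved, and 0 fell (4 and 0 list-adjusted, 5 and 0 unadjusted, 4 and 0 by DESeq2, 4 and 0 by voom, 4 and 0 in the 4 libraries). The tryptophan oxygenase gene v rose 2.30-fold and xanthine dehydrogenase, ry, 1.80-fold. Camera called the list (median 0.03, −0.06 to 0.09 with 1 library left out, camera adjusted p = 0.0273, adjusted p = 0.917 with an estimated correlation, Fisher's exact test adjusted p = 0.0119). Both tests include w, with a log2 fold change of 3.93, and neither was run without it. How far they rest on w is therefore not known. The camera call ended without wBerlin replicates 2 or 3 (0.194 and 0.0753) or Kdm3 KO replicates 1 or 3 (0.118 and 0.220), with the replicate block and with the filter of 5 CPM (0.0622 and 0.0616, range 8.35e-05 to 0.220 over 10 alternatives). Of 40 genes on the phototransduction list 3 fell and 0 rose (3 and 1 list-adjusted, 4 and 1 unadjusted, 3 and 1 by DESeq2, 3 and 0 by voom, 2 and 4 in the 4 libraries). These were the cuticular protein gene Cpr72Ec, Rh5 and inaF-B at 0.48, 0.56 and 0.53 of the control level. The call of Rh5 ended without wBerlin replicate 2 or Kdm3 KO replicates 2 or 3 (adjusted p 0.0758, 0.0564 and 0.0810) and in the 4 libraries (0.0506). That of inaF-B ended without wBerlin replicate 2 or Kdm3 KO replicate 3 (adjusted p 0.0765 and 0.0830). Only 1 member fell without wBerlin replicate 2 or Kdm3 KO replicate 3, and 1 rose without Kdm3 KO replicate 1. The phototransduction median was −0.01, −0.10 to 0.07 with 1 library left out, and above 0 with total count scaling (0.0079). Camera did not call the list (camera adjusted p = 0.302), except as lower without wBerlin replicates 2 or 3 or Kdm3 KO replicate 1 (0.0361, 0.00406 and 0.0120) and as higher in the 4 libraries (0.000364, range 0.000364 to 0.551 over 10 alternatives).

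Of 28 clock genes 2 fell, the repressor gene vri at 0.64 of the control level (adjusted p = 0.0114) and takeout, and 0 rose (3 and 0 list-adjusted, 5 and 1 unadjusted, 4 and 0 by DESeq2, 2 and 0 by voom, 3 and 0 in the 4 libraries). The number of lower members was 4 without wBerlin replicate 1 and 1 without wBerlin replicate 2 or Kdm3 KO replicates 2 or 3. The call of takeout ended without wBerlin replicates 1 or 2 or Kdm3 KO replicates 2 or 3 (adjusted p 0.0541, 0.108, 0.0776 and 0.115) and in the 4 libraries (0.107). Camera called the clock list (median −0.07, −0.14 to −0.03 with 1 library left out, camera adjusted p = 0.0136, adjusted p = 0.867 with an estimated correlation). That call was lost without Kdm3 KO replicate 2 (0.375), in the 4 libraries (0.540) or with the filter of 5 CPM (0.0606, range 0.000486 to 0.540 over 10 alternatives).

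Among chromatin genes, windei, wde (arm 2R, 10800420 to 10808938), whose product binds the H3K9 methyltransferase Eggless, fell 1.66-fold from 77.1 ± 4.34 to 46.4 ± 2.47 CPM (SD, n = 3, adjusted p = 0.00353). It was the only 1 of 44 heterochromatin genes that fell, with 0 higher (1 and 0 list-adjusted, 1 and 0 unadjusted, 1 and 0 by DESeq2, 1 and 0 by voom, 1 and 0 in the 4 libraries). Camera called that list (median −0.07, −0.14 to −0.06 with 1 library left out, camera adjusted p = 0.0232, adjusted p = 0.595 with an estimated correlation). This call ended without Kdm3 KO replicate 2 or in the 4 libraries (0.124 and 0.206, range 0.00136 to 0.206 over 10 alternatives). Of 15 histone demethylase genes only Kdm3 itself fell and 0 rose (1 and 0 list-adjusted, 1 and 0 unadjusted, 1 and 0 by DESeq2, 1 and 0 by voom, 1 and 0 in the 4 libraries). Camera called the list with Kdm3 in it lower (camera adjusted p = 0.0232, adjusted p = 0.704 with an estimated correlation). This call ended without Kdm3 KO replicate 2 or in the 4 libraries (0.289 and 0.260, range 0.00499 to 0.289 over 11 alternatives). Without Kdm3, whose fall the design gives, camera did not call the 14 other demethylase genes (median −0.08, camera adjusted p = 0.127, adjusted p = 0.963 with an estimated correlation), in a test added after the data were seen. Of 33 histone methyltransferase genes 1 fell, the arginine methyltransferase gene Art3 at 0.68 of the control level (adjusted p = 0.0223), and 0 rose (1 and 0 list-adjusted, 8 and 0 unadjusted, 1 and 0 by DESeq2, 1 and 0 by voom, 3 and 0 in the 4 libraries). Camera called this list lower too (median −0.13, −0.17 to −0.10 with 1 library left out, camera adjusted p = 0.00183, adjusted p = 0.595 with an estimated correlation). The call of Art3 ended without wBerlin replicate 2 or Kdm3 KO replicates 1 or 3 (adjusted p 0.0508, 0.0972 and 0.0520), where 0 members fell, and 2 fell without wBerlin replicate 1.

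Of 81 nuclear oxidative phosphorylation genes UQCR-11 fell 1.49-fold and 0 rose (1 and 0 list-adjusted, 2 and 1 unadjusted, 1 and 0 by DESeq2, 1 and 0 by voom, 2 and 0 in the 4 libraries). The list had a median of 0.03, −0.05 to 0.04 with 1 library left out (camera adjusted p = 0.734). The UQCR-11 call ended without Kdm3 KO replicate 3 (adjusted p 0.0806), and 2 genes fell without wBerlin replicate 1. Of 86 ribosomal protein genes edgeR called 0 (0 and 0 list-adjusted, 4 and 2 unadjusted, 1 and 2 by DESeq2, 1 and 0 by voom, 6 and 0 in the 4 libraries). The gene RpS29 had a log2 fold change of 0.51 (adjusted p = 0.0539), and it rose by DESeq2, limma voom, with RLE, upper quartile and total count scaling, the filter of 5 CPM and the replicate block, and in the 4 libraries (adjusted p 8.56e-05, 0.0439, 0.0434, 0.00889, 0.00760, 0.00747, 0.0411 and 0.00787). Without Kdm3 KO replicate 2 it rose (adjusted p = 0.00612) as 1 of 5 genes, while 1 fell without wBerlin replicates 1 or 3. RpS5b went the other way, with a log2 fold change of −2.13 (adjusted p = 0.0748). It was at 5.28, 8.69 and 1.69 CPM in wBerlin replicates 1, 2 and 3. It fell by DESeq2, with the replicate block and without wBerlin replicate 3 (adjusted p 0.000659, 0.004355 and 0.0237). Camera called the ribosomal protein list higher (median 0.12, 0.06 to 0.22 with 1 library left out, camera adjusted p = 0.00114, adjusted p = 0.917 with an estimated correlation). The ribosomal call ended without Kdm3 KO replicates 1 or 3 (0.168 and 0.260, range 3.03e-17 to 0.260 over 10 alternatives). Of 7 tested histone genes edgeR called 0 (0 and 0 list-adjusted, 0 and 1 unadjusted, 0 and 0 by DESeq2, 0 and 0 by voom, 0 and 0 in the 4 libraries), with a median of −0.18, −0.29 to −0.15 with 1 library left out. Camera did not call them (camera adjusted p = 0.0662), except without wBerlin replicate 3 or Kdm3 KO replicate 1 (0.0255 and 0.0238, range 0.0238 to 0.545 over 9 alternatives).

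Called genes were more frequent near Kdm3 on arm 3R. Within 2 Mb of Kdm3, 27 of 521 tested genes were called (5.18%), against 399 of 13459 elsewhere (2.96%). The odds ratio was 1.79 (95% confidence interval 1.15 to 2.675, Fisher's exact test p = 0.00859, adjusted p = 0.0494). These genes included CG4757 (11161207 to 11163498), which rose 25.7-fold, CG16789 (9566195 to 9569189), which rose 4.41-fold, the one-carbon gene pug, and Os-C. Gnmt lay 3.16 Mb from Kdm3, outside that window. Fisher's exact test treats genes as independent. The calls in the window include close neighbours, such as Ugt35C1, Ugt302K1, Ugt35B1 and Ugt35A1, so its p may be too small. Called genes were less frequent on arm 3L than elsewhere, 66 of 2809 (odds ratio 0.723, 95% confidence interval 0.545 to 0.945, Fisher's exact test adjusted p = 0.0494), and arms 2L, 2R, 3R and X did not pass (adjusted p 0.072, 0.903, 0.0723 and 0.072). The unadjusted p of the 2 Mb window was above 0.05 without wBerlin replicates 2 or 3 (odds ratio 1.62 and 1.54, Fisher's exact test p = 0.0846 and 0.0814) and without Kdm3 KO replicates 1 or 3 (odds ratio 1.65 and 1.47, p = 0.05025 and 0.183). Within 1 Mb the odds ratio was 1.33 (Fisher's exact test p = 0.372). With calls of at least 2-fold it was 1.93 within 2 Mb (Fisher's exact test adjusted p = 0.0731) and 0.682 on arm 3L (Fisher's exact test adjusted p = 0.106), so that neither passed.

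**Figure D3:**
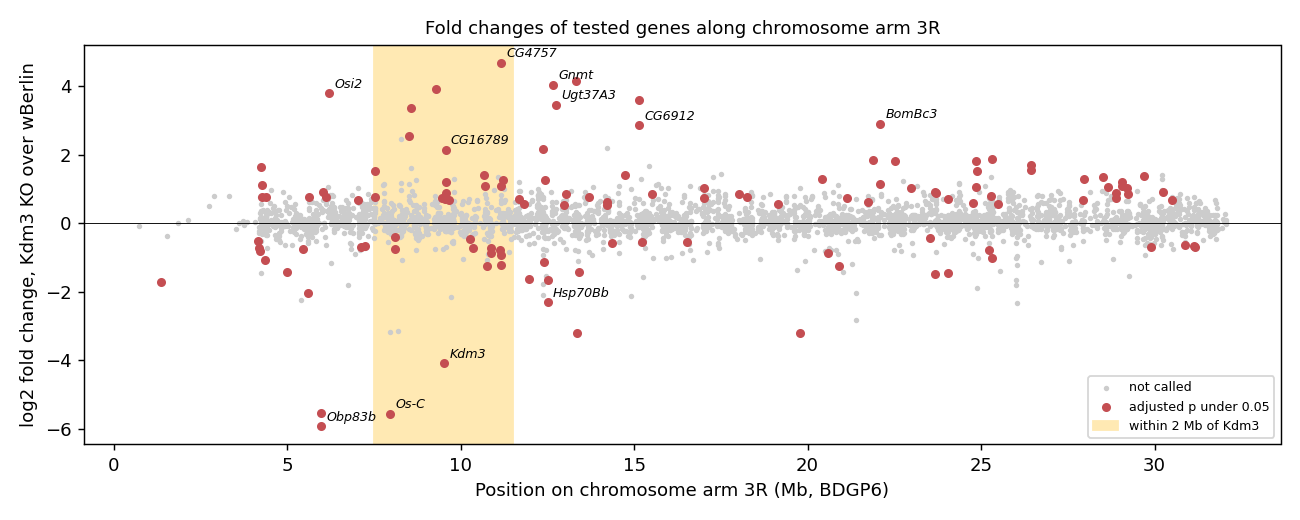
Log2 fold change (Kdm3 KO over wBerlin, vertical axis) of tested genes against position on chromosome arm 3R in Mb (BDGP6), with called genes in red, others in grey, and the window within 2 Mb of Kdm3 shaded. Within the window 27 of 521 tested genes were called, and Gnmt lies to its right, 3.16 Mb from Kdm3.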

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

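The fit of 4 libraries, without wBerlin replicate 1 and Kdm3 KO replicate 2, and the lists with members taken out were chosen only after the data were seen, and the other alternatives were planned. Of 77 named genes 62 were called, and all 62 kept their direction in each of the 16 alternatives that tested them, while 34 of them stayed called in each. Among 1218 comparisons of named genes with an alternative, 128 lost and 50 gained a call, and 1 turned, VGlut without wBerlin replicate 2 (log2 fold change −0.0366, range −0.0366 to 0.1545 with 1 library left out). The filter of 5 CPM left 14 named genes and the female-enriched, gut and histone lists without a value. The causes of the changes below were not tested, apart from fewer genes or libraries where the setting removes them. The 432 calls (303 higher, 129 lower) became 916 (514 and 402) with DESeq2 and 768 (492 and 276) with the filter of 5 CPM. Upper quartile scaling gave 212 lower genes, and no filter on low counts 266. The stricter thresholds left 207 (158 and 49) at 2-fold and 167 (130 and 37) at an adjusted p under 0.01. Leaving out 1 library gave 243 to 735 calls, 181 to 574 of them higher and 62 to 467 lower. Of all calls 70.1% were higher, against 56.1% with DESeq2, 51.8% with no filter and 36.5% without wBerlin replicate 1. With the replicate number as a block the test made 779 calls (362 lower, 53.5% higher), including 430 of the 432. Whether the numbers mark a shared batch stays open. Same-numbered libraries deviated from their group means with correlations of 0.34, 0.25 and −0.05 for replicates 1, 2 and 3, and 4 of 6 correlated best with their own number. The 4 libraries gave 1082 calls (606 and 476). With an estimated correlation, or with directional fry, 0 of the 15 list calls remained. With the Bomanin and Daisho genes taken out of the immune list, the fat body genes out of the female-enriched list and Kdm3 out of the histone demethylase list, 13 lists were called. In the 4 libraries the synapse, phototransduction, gut, chemoreceptor and neuropeptide lists, each called before or after, turned direction (camera adjusted p 0.22, 0.000364, 0.106, 1.34e-05 and 0.0365), and without Kdm3 KO replicate 2 the gut and chemoreceptor lists did (0.3385 and 0.001316, ranges 9.133e-05 to 0.3385 and 0.001316 to 0.9939 with 1 library left out). Lists called neither before nor after turned as well. In the 4 libraries these were the alcohol and male-enriched lists (0.0941 and 0.423). Without Kdm3 KO replicate 2 they were the phototransduction, alcohol, male-enriched, odorant-binding and neuropeptide lists (0.433, 0.4395, 0.7335, 0.747 and 0.548). With other libraries left out, lists of GABA, monoamine, acetylcholine, nuclear oxidative phosphorylation, phototransduction, odorant-binding and neuropeptide genes turned (0.133 to 0.999). The filter of 5 CPM turned the odorant-binding, chemoreceptor and neuropeptide lists (0.861, 0.241 and 0.945), and directional fry the odorant-binding and neuropeptide lists (0.853 and 0.868). The odds ratio of calls near Kdm3 was 1.33 within 1 Mb and 1.47 to 1.65 with 1 library left out, over all 6 such fits. Depth limits what can be said of genes near 0.106 to 0.151 CPM, the level of 3 counts.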

Other observations

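The lists of purine synthesis, amino acid metabolism, Bomanin and Daisho, soluble antennal, antennal receptor, Johnston's organ and maxillary palp genes were chosen only after the data were seen, as were the tests of the genotype for the antennal genes, of linked sequence for Gnmt and of a larger female share. The p-values of these lists come from the data that led to them and are no separate support. Genes of de novo purine synthesis, none of which is in the one-carbon or fat body lists, were higher in Kdm3 KO. Of 11 tested, 5 rose and 0 fell (7 and 0 list-adjusted, with p adjusted over the list alone, 7 and 0 at an unadjusted p under 0.05, 7 and 0 by DESeq2, 5 and 0 by voom, 7 and 0 in the 4 libraries). Gart rose 3.02-fold from 162 ± 25.5 to 487 ± 111 CPM (SD, n = 3, adjusted p = 0.00255), and Paics, Pfas, CG11089 and Adsl rose 2.78-, 2.85-, 2.89- and 2.05-fold. Prat2, which codes for the first enzyme of the pathway, did not pass (log2 fold change 0.79, adjusted p = 0.117), nor did its paralog Prat (−0.03, adjusted p = 0.9405). Of 19 genes of amino acid metabolism 13 rose and 0 fell (15 and 0 list-adjusted, 15 and 0 unadjusted, 14 and 0 by DESeq2, 12 and 0 by voom, 13 and 0 in the 4 libraries), among them Hn, Tdh (2.04-fold), Hao (2.29-fold), Agxt (2.08-fold) and P5CS (1.96-fold). That count was 8 without wBerlin replicates 1 or 3 or Kdm3 KO replicates 1 or 3.

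All 15 tested Bomanin and Daisho genes rose, by 2.21-fold (BomT3) to 7.51-fold (BomBc3), and 11 of them are also in the immune list. DESeq2 and voom called all 15 too. The call of BomT3 ended without wBerlin replicates 1 or 3 (adjusted p 0.0566 and 0.0862), and that of Bbd without wBerlin replicate 2 (adjusted p 0.0664). Their summed level was 808, 913 and 795 CPM in wBerlin replicates 1, 2 and 3 and 2541, 2082 and 4110 CPM in Kdm3 KO. Camera called the purine, amino acid and Bomanin and Daisho lists (adjusted p 9.16e-08, 5.57e-17 and 5.55e-30), and none of these 3 with an estimated correlation (adjusted p = 0.322, 0.229 and 0.182). Their median log2 fold changes were 0.79, 0.78 and 1.86, against 0.47 for the fat body list with an upper quartile of 1.22, so a larger share of fat body RNA was not excluded for the purine and amino acid genes. Of 9 genes of Johnston's organ, which lies in the antenna, edgeR, DESeq2 and voom called 0 (0 higher and 2 lower at an unadjusted p under 0.05, camera adjusted p = 0.0221, adjusted p = 0.581 with an estimated correlation). Of these, 1 fell without wBerlin replicate 1 and 5 in the 4 libraries left without wBerlin replicate 1 and Kdm3 KO replicate 2, a fit also chosen after the data were seen. Their median log2 fold change was −0.25, and −0.63 in the 4 libraries. Of 38 antennal receptor genes 1 rose, Or82a, and 0 fell (1 and 1 list-adjusted, 1 and 3 unadjusted, 1 and 1 by DESeq2, 0 and 0 by voom, 1 and 9 in the 4 libraries). Lower genes numbered 2 without wBerlin replicate 1 and 1 without Kdm3 KO replicate 2. Their median log2 fold change was −0.08 (camera adjusted p = 0.211), but −0.30 without wBerlin replicate 1, −0.56 without Kdm3 KO replicate 2 and −0.80 in the 4 libraries. Against wBerlin replicates 2 and 3 the median log2 ratio over these receptors was −0.468, 0.296 and −0.711 in Kdm3 KO replicates 1, 2 and 3, with 32, 14 and 33 of 38 lower. Their summed level was 59.0, 98.0 and 116 CPM in wBerlin replicates 1, 2 and 3 and 57.3, 95.6 and 51.2 CPM in Kdm3 KO. That of the 8 soluble antennal genes was 39.3, 257 and 366 CPM in wBerlin and 10.4, 27.0 and 19.4 CPM in Kdm3 KO. That of the 6 palp receptors was 13.2, 12.4 and 14.7 CPM in wBerlin and 13.4, 20.4 and 13.3 CPM in Kdm3 KO.

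The first pattern is the low level of antennal genes in Kdm3 KO and in wBerlin replicate 1: 7 of 8 soluble antennal genes fell by edgeR and 0 by voom (camera adjusted p = 0.000329, adjusted p = 0.407 with an estimated correlation), with 3 lower without wBerlin replicate 2 or Kdm3 KO replicate 3 and 4 without wBerlin replicate 3 or Kdm3 KO replicate 2. A loss of antennae from the heads stays open. The 38 antennal receptors had a median log2 ratio of −0.60 between wBerlin replicate 1 and replicates 2 and 3, with 33 lower. This lies between the 2 bounds set for this test, −1 and −0.5. A pseudocount of 0.25 CPM in these ratios pulls those of genes at low levels towards 0. Kdm3 KO replicate 2 was low in soluble antennal genes but not in the median of these receptors (log2 ratio 0.296). That library cannot decide the question. Orco was low in it (5.73 CPM against 26.5 and 37.0 CPM in wBerlin replicates 2 and 3). Palp receptors were high in it, and its summed chemoreceptor list was 494 CPM against 292 to 409 CPM in the others. An effect of the genotype stays open too: over the 7 genes wBerlin replicate 1 lay at a median log2 ratio of −3.14 to replicates 2 and 3, a difference within 1 genotype, yet all 7 were lower still in each Kdm3 KO library (median log2 ratio −2.02 to wBerlin replicate 1). These 2 sources may act together and cannot be told apart, since whether antennae stayed on the heads is not given in the sources used here and 1 control library carries the contrast. A change of chemosensory genes beyond the antenna stays open as well: the 6 palp receptors, of which 0 passed edgeR, DESeq2, voom or an unadjusted p under 0.05, had a median log2 fold change of 0.28 (camera adjusted p = 0.230), 0.02 without Kdm3 KO replicate 2 and −0.06 in the 4 libraries, but the bound of −0.5 set for them was also met by the antennal receptors (−0.08), which lay below it only without Kdm3 KO replicate 2 (−0.56) and in the 4 libraries (−0.80), and the 6 genes summed to 20.4 CPM or less.

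The second pattern is the rise of one-carbon genes beside fat body genes. A larger share of fat body RNA is argued against as the source for Gnmt, whose log2 fold change exceeded the 90th percentile of the fat body list by 2.38 (SE 0.32), but it stays open for the other one-carbon genes, whose median lay 0.01 from that of the fat body list. The RNAs roX1 and roX2, which males express, go against a larger share of female heads. Their mean log2 fold change was 0.50 (SE 0.09, which treats the 2 as independent), but neither passed the test alone. Other values go with such a share, so it is not excluded. Yp3 and fit rose, and Yp1 and Yp2 had log2 fold changes of 0.83 and 0.81 without passing (adjusted p 0.0705 and 0.082). Of 18 female-enriched genes 17 had a positive log2 fold change. Sequence linked to the Kdm3 allele that acts on genes near it is argued against for the set, since 8 of the 10 called one-carbon genes lie on arms other than 3R. This count cannot address linked sequence that acts on genes of other arms. Nor can it address differences between the stocks elsewhere in the genome, which this design cannot tell apart from the loss of Kdm3. For Gnmt linked sequence cannot be told apart from an effect of Kdm3 loss. Gnmt lies 3.16 Mb from Kdm3, and calls within 5 Mb were more frequent (odds ratio 1.58, 95% confidence interval 1.17 to 2.10). Higher calls of at least 2-fold, to which Gnmt belongs, gave an odds ratio of 1.21 with an interval of 0.681 to 2.01 (Fisher's exact test p = 0.485). That interval also covers 1.58, so it does not decide the question. Among the 10 largest increases, CG4757, Gnmt, Osi2 and CG45080 lie within 5 Mb of Kdm3, and the rest do not.

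The third pattern is the level of Kdm3 in Kdm3 KO replicate 1, 3.86 CPM against 0.642 and 0.710 CPM. Control RNA mixed into that library would have to make up 10.7% of it. The 41 other genes at least 2-fold lower gave a median share of −0.1% (quartiles −10.4% and 14.4%). Of these genes 20 gave a positive share, and the median lay near 0 rather than near 10.7%. The quartiles describe the spread between single genes and cover both values, so mixing is not excluded. It cannot be told apart from residual transcripts of the allele, which no test addressed.

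The 6 libraries can be split into 3 and 3 in 10 ways, so the share is never under 0.1. The real split gave 432 calls and the highest of the others 0, so that 1 of 10 splits reached the real number. For the lists called by camera with the preset correlation, the real split gave 15 and the highest other 19, and 5 of 10 splits reached the real number.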
